A study of Homo sapiens with 12 samples.

How the data were processed

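RNA was extracted with TRIzol from HEK293T cells carrying the EZH2 hairpin, per the labels' protocols, and sequenced by a commercial provider. The library kit and its strand setting are not given in the sources used here. Samples were grouped by the labels into individual (control) or dual-specificity aptamers and Wnt- or Wnt+ medium, 4 groups of 3 libraries. The authors name Trim Galore, HISAT2, featureCounts, DESeq2 and the genome GRCh38.p13, per the submitters' processing notes, without versions, settings or the step each was used for. The deposited count table was not used here, because the names of its 12 columns match no label and assigning them by order or by values would be a guess. Depth per library, and the comparisons of Wnt+ with Wnt- medium, were therefore not analysed here.

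The values used are those of 2 deposited DESeq2 tables, 1 per medium, with log2 fold changes, their standard errors, the Wald statistic as a score, p-values and adjusted p-values, per the file headers. The authors' deposited tables also give baseMean, the mean of normalised counts per gene, per the file headers. The statistic equals the log2 fold change divided by its standard error in all 30999 genes with a p-value of the deposited tables. Whether the folds were shrunken is not given in the sources used here. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over the genes that have one, 30999 in Wnt- and 16731 in Wnt+. Mean counts are identical in both tables, so the fits share their libraries. How the model was set up is not given in the sources used here. That each table compares the dual-specificity with the control aptamers within its medium was read from the table names together with the labels. Which arm is the numerator is not written, so the sign of a fold has no arm attached, and the same numerator in both tables is an assumption.

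Each table held 61022 entries for 60683 Ensembl IDs, and the 339 repeats of an ID with several symbols were dropped. Symbols came from a reference list of gene names, or from the deposited tables where that list had none. Coordinates, and the length and GC content of each gene's longest transcript, came from GENCODE 29. Adjusted p-values under 0.05 in the deposited tables were taken as calls, and 95% intervals were computed here from fold and standard error. The difference between the tables was tested here as a z score, the difference of the log2 folds over the root of the summed squared standard errors, adjusted over the 16897 genes with a mean count of at least 10. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, with a preset correlation of 0.01, adjusted over the 31 of 32 lists with at least 5 measured genes. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The list test and the difference test were checked on simulated data. With no change simulated, 3.29% of list p-values fell under 0.05. The simulated genes were independent, so lists of correlated genes were not checked. With only a length trend simulated, the ribosomal protein list had p under 0.05 in 76% of runs, and in 2% with the trend removed. The simulated trend used the same length values that were then removed. It therefore cannot tell whether a trend with another measure of length would be removed. The difference test recovered 20.1%, 57.5% and 72.8% of genes changed by log2 0.3, 0.6 and 1.0, with 4.12% of its calls false. Its simulated errors followed the deposited standard errors, whereas the real statistics had robust SDs of 1.17 in Wnt- and 0.739 in Wnt+. These rates may therefore not hold for the data.

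The comparisons, the lists, the thresholds and the naming rule were written before the data were examined. Named genes are the 12 largest positive and negative calls with a mean count of at least 56.9, the 10 smallest p-values where fewer than 5 genes pass, up to 4 members of a list with the smallest p, and 10 genes fixed by name. Some genes that the rule names are not reported here. The planned edgeR fit and camera test on the counts of all 12 libraries were not run. Since the counts could not be tied to samples, the authors' deposited DESeq2 results, the z test and cameraPR took their place, the abundance limit was put on the mean count, and the planned requirement that the libraries of the arms not overlap could not be checked. Of 889 list entries 882 matched an ID and 732 reached the mean count limit. Alternatives tried were other filters and thresholds, the statistic divided by its robust SD, its ranks, a preset correlation of 0.05, the signs of one table turned, and a spline fit (5 degrees of freedom) of transcript length, GC content and mean count removed from the statistic.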

Results

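RNA abundance was measured by sequencing in HEK293T cells, a human embryonic kidney line. All cells stably carried a short hairpin RNA against EZH2, the catalytic methyltransferase subunit of Polycomb repressive complex PRC2. The cells were transfected with 1.5 µg of plasmid encoding RNA aptamers, short structured RNAs that bind chosen proteins. One arm received the individual (control) aptamers and the other the dual-specificity aptamer, which by the series title raises O-GlcNAc, a single-sugar protein modification, on beta-catenin. Beta-catenin is the transcriptional effector of canonical Wnt signalling. At 20 hr after transfection the medium was exchanged for regular medium (Wnt-) or for medium with 50% Wnt3A-conditioned medium (Wnt+), and cells were lysed 4 hr later, at 24 hr. The 12 libraries fall into 4 groups of 3, one group for each aptamer in each medium. The labels do not say whether the 3 libraries of a group were separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical.

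The values come from 2 tables of DESeq2 results, one per medium, read here as the comparison of the aptamer arms within that medium. Neither table writes which arm is the numerator, so fold changes are given as positive or negative and not as higher in one arm. Every comparison of signs or sizes between the media assumes that both tables have the same numerator. The mean normalised counts per gene sum to 28467948 over 30999 genes with a mean above 0, and 16897 genes had a mean count of at least 10. Total counts of single libraries are not reported here. The precision follows the depth of each gene. In Wnt- medium the median 95% interval of a log2 fold change was ±0.12 for genes with a mean count above 1000 and ±0.68 for genes with a mean count of 10 to 100.

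The first question was whether the genes of the pathway under study differed between the aptamer arms. EZH2 (ENSG00000106462, chromosome 7, 148807383 to 148884321) had a log2 fold change of -0.07 (SE 0.07) in Wnt- and -0.04 (SE 0.07) in Wnt+ in the authors' deposited tables. Since every library carried the hairpin, these values bear on the aptamers and not on the depth of the knockdown. CTNNB1 (ENSG00000168036, chromosome 3, 41194741 to 41260096), which encodes beta-catenin, stood at 0.01 (SE 0.04) and -0.01 (SE 0.04) in the authors' deposited tables. OGT, the enzyme that adds O-GlcNAc, stood at 0.01 and -0.04 (SE 0.05 in both), and OGA, the enzyme that removes it, at 0.04 and -0.00 (SE 0.05 in both), again in the authors' deposited tables. The Wnt feedback target AXIN2 had folds of -0.09 (SE 0.08) and -0.08 (SE 0.07) in the authors' deposited tables for Wnt- and Wnt+. LEF1, NKD1, MYC and CCND1, further Wnt targets, lay between -0.10 (MYC, Wnt+) and 0.06 (LEF1, Wnt-) in the authors' deposited tables. None of these 9 genes (0 with an unadjusted p under 0.05) passed an adjusted p of 0.05 (DESeq2), and SP5 was listed with a mean count of 0. The widest of their 95% intervals ran from -0.28 to 0.08 (MYC, Wnt+), computed from the fold and standard error in the authors' deposited table.

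**Figure D1:**
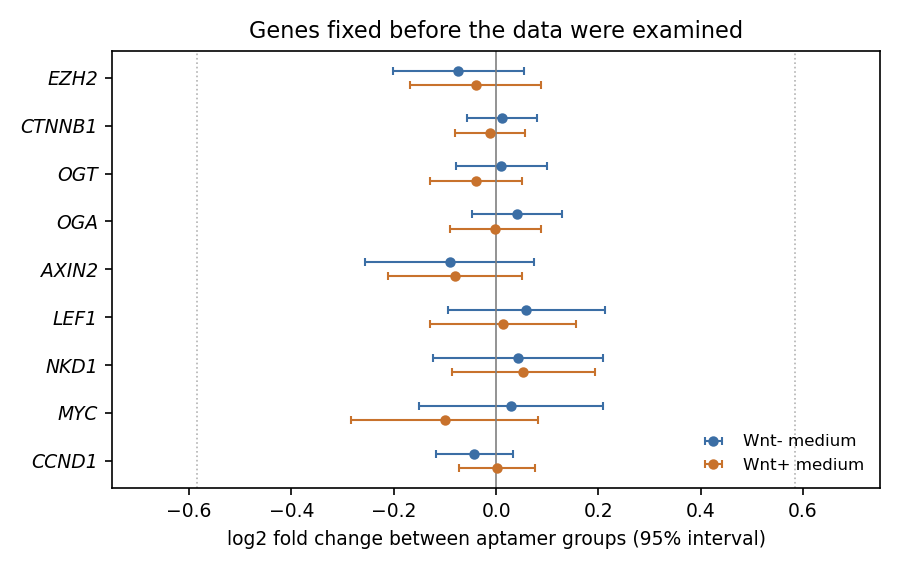
Log2 fold change between the aptamer arms (x axis) of 9 genes fixed before the data were examined, in Wnt- (blue) and Wnt+ (orange) medium, from the authors' deposited tables. Bars are 95% intervals and dotted lines mark a fold of 1.5 in either direction. Every interval includes 0 and lies inside the dotted lines.

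The wider gene lists of the pathway gave the same picture. Of 30 measured Wnt/beta-catenin target genes, 0 passed the DESeq2 threshold in either medium, and 4 in Wnt- and 1 in Wnt+ had an unadjusted p under 0.05. The median log2 fold change of that list was -0.00 in Wnt- (adjusted p = 0.937, cameraPR) and 0.01 in Wnt+ (adjusted p = 0.634). MSX1, a homeodomain factor, had the smallest p in Wnt+, with 0.31 (SE 0.10, adjusted p = 0.196) in the authors' deposited table, and it was the 1 member past an adjusted p of 0.05 when adjusted over the list alone. All 30 members had 95% intervals inside a log2 fold of ±1 in both media. The 38 Wnt pathway components had medians of 0.03 (adjusted p = 0.115) and 0.01 (adjusted p = 0.454). The 13 PRC2 subunits had medians of -0.02 in Wnt- (adjusted p = 0.972) and -0.01 in Wnt+ (adjusted p = 0.886). The 12 genes of O-GlcNAc cycling and the hexosamine pathway, which makes the sugar donor, had medians of 0.00 in Wnt- (adjusted p = 0.937) and -0.04 in Wnt+ (adjusted p = 0.107).

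The second comparison was between the aptamer arms in regular medium. NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725), a nuclear receptor that represses transcription in the circadian clock, was the 1 gene past the threshold. Its log2 fold change was 0.52 (SE 0.10), a fold of 1.43, with an adjusted p of 0.0158 in the authors' deposited table. The 3' end of NR1D1 overlaps THRA on the opposite strand, and the strand setting of the counting is not given in the sources used here, so the assignment of these reads is uncertain. THRA itself, looked up after the values of NR1D1 were seen, had a fold of -0.01 (SE 0.06) in the authors' deposited table for Wnt-. NDUFA3 (ENSG00000170906, chromosome 19, 54102728 to 54109257), a subunit of respiratory complex I, came next with -0.40 (SE 0.09) and an adjusted p of 0.0742 in the authors' deposited table. The 10 smallest p-values also included 5 named protein-coding genes with negative folds between -0.33 and -0.29 in the authors' deposited table: OCIAD2, HSD17B10, BRK1, DNPH1 and COX7A2, the last a subunit of cytochrome c oxidase. SNHG19, a small nucleolar RNA host gene, had -0.42 (SE 0.12), and the mitochondrially encoded MT-ND4 had 0.22 (SE 0.06), both at an adjusted p of 0.684 in the authors' deposited table. The largest fold among the 10 was positive, 1.80 (SE 0.45, adjusted p = 0.546) in the authors' deposited table, for a noncoding RNA without a symbol (ENSG00000267939) with a mean count of 20.8. At an unadjusted p under 0.05, 580 genes had positive and 1066 negative folds among the 16897 genes, where chance gives 845 in all.

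Cytosolic ribosomal protein genes lay together on the negative side in regular medium. Of the 70 measured cytosolic ribosomal protein genes, 69 had a negative fold, with a median log2 fold change of -0.26 (quartiles -0.29 and -0.21). RPL23A had -0.26 (SE 0.08), RPS23 -0.27 (SE 0.08) and RPL18 -0.27 (SE 0.08) in the authors' deposited table. As a list they differed from other genes (adjusted p = 2.49e-32, cameraPR over 31 lists, and 2.2e-12 with a preset correlation of 0.05). List p-values here rest on a preset correlation between genes. They do not measure how a list varies between the libraries of a group. Singly, 0 of the 70 passed the DESeq2 threshold over all genes, 57 had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. The shift is relative to other genes, whose median DESeq2 scaling holds near 0 (0.0020). The median of genes followed transcript length, from -0.06 for the shortest genes (median 1000 nt) to 0.06 for the longest (median 7357 nt; Spearman rho across genes of the statistic with length 0.344; genes are not independent replicates). With that trend, GC content and mean count removed from the statistic, the ribosomal protein list was still called (adjusted p = 1.91e-13). Ribosomal protein genes share reads with their pseudogenes, so values of single members are uncertain.

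Transcripts encoded by the mitochondrial genome moved the other way in regular medium. Of 15 such transcripts, 14 had positive folds with a median of 0.15 (adjusted p = 5.62e-08, cameraPR), and 7 passed when adjusted over the list alone, against 0 over all genes and 8 at an unadjusted p under 0.05 (DESeq2). MT-ND5 had 0.19 (SE 0.07), MT-ND1 0.18 (SE 0.07) and MT-CYB 0.15 (SE 0.06) in the authors' deposited table. A share of mitochondrial transcripts that moves with an arm is also a marker of RNA quality, and it moved here together with the ribosomal protein list.

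Smaller negative shifts were seen in 5 further lists. The 16 glycolysis genes had a median of -0.10 (adjusted p = 4.66e-05), with PGAM1 at -0.15 (SE 0.06), GAPDH at -0.17 (SE 0.07), ENO1 at -0.14 (SE 0.06) and TPI1 at -0.18 (SE 0.08) in the authors' deposited table. The 36 genes of the integrated stress and amino acid response, which ATF4 drives, had a median of -0.09 (adjusted p = 5.78e-05). DDIT4 stood at -0.23 (SE 0.08), VEGFA at -0.19 (SE 0.06) and ATF4 at -0.18 (SE 0.07) in the authors' deposited table. Unadjusted p-values under 0.05 with a negative fold were found for 7 genes in each of these lists, and no member passed the DESeq2 threshold or the adjustment over the list alone (0 genes). Heat shock genes (median -0.08, adjusted p = 0.00883), ribosome biogenesis genes (median -0.07, adjusted p = 0.0174) and S phase genes (median -0.04, adjusted p = 0.0312) were also called. These 3 calls were lost with a preset correlation of 0.05 (adjusted p = 0.0602, 0.161 and 0.267) and with the length, GC content and count trend removed (adjusted p = 0.627, 0.613 and 0.956). The other 24 tested lists were not called in regular medium, the lowest adjusted p being 0.0977 for unfolded protein response chaperones. Interferon-stimulated and RNA-sensing genes, which respond to foreign RNA, had a median of 0.00 in Wnt- (adjusted p = 0.937) and 0.02 in Wnt+ (adjusted p = 0.886).

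**Figure D2:**
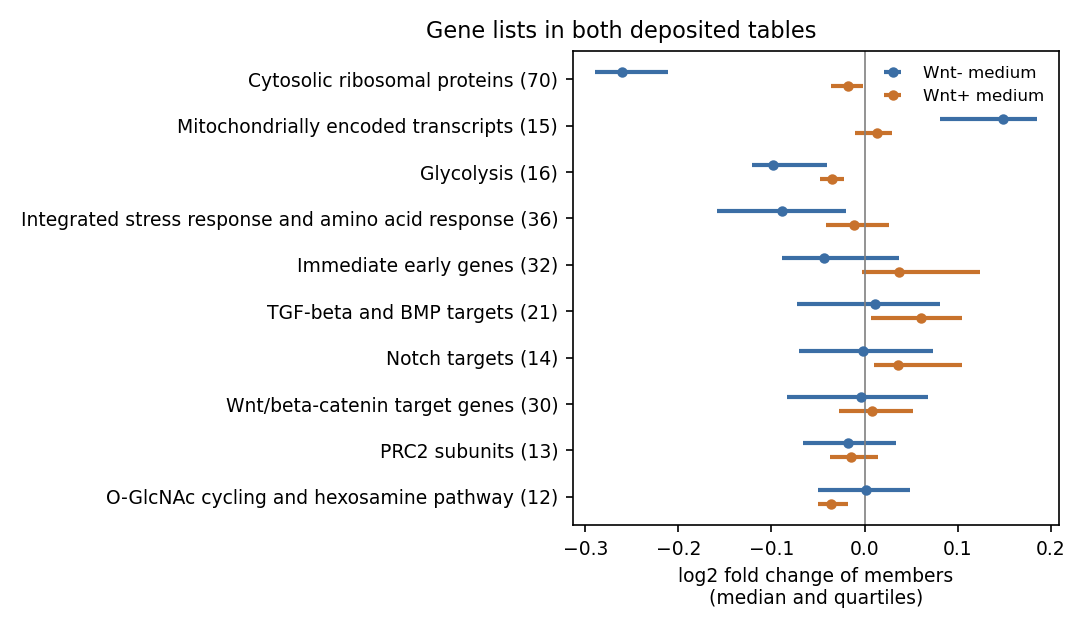
Median (point) and quartiles (bar) of the log2 fold changes of the members of 10 gene lists fixed before the data were examined, in Wnt- (blue) and Wnt+ (orange) medium, with the number of measured genes in parentheses. The ribosomal protein genes sit at -0.26 in Wnt- and at -0.02 in Wnt+, and the mitochondrially encoded transcripts at 0.15 and 0.01.

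The third comparison was between the same arms under Wnt3A-conditioned medium. Here 73 genes passed the threshold, 72 with a positive and 1 with a negative fold change, and 70 of them were annotated as protein coding. The largest positive fold among genes above the abundance limit was that of PXMP2 (ENSG00000176894, chromosome 12, 132687606 to 132704991), a peroxisomal membrane channel protein. Its log2 fold change was 1.79 (SE 0.24), a fold of 3.46, with an adjusted p of 5.38e-10 in the authors' deposited table. CENPV, a centromere protein, had 1.24 (SE 0.25, adjusted p = 0.000849), ZNF503, a zinc finger repressor, 1.23 (SE 0.25, adjusted p = 0.000604) and NDST2, a heparan sulfate sulfotransferase, 1.18 (SE 0.25, adjusted p = 0.00196) in the authors' deposited table. C4orf48 had 1.14 (SE 0.22) and ETS2 (ENSG00000157557, chromosome 21, 38805307 to 38824955), an ETS family transcription factor, 1.04 (SE 0.18), with adjusted p of 0.000247 and 8.88e-06 in the authors' deposited table. The rest of the 12 largest were NOCT, a deadenylase-family protein with a daily rhythm, at 0.99, SH3RF3-AS1 at 0.89, PTP4A2, a phosphatase, at 0.88, ANKRD6 at 0.78, LINC00674 at 0.72 and 1 gene without a symbol, with SE between 0.11 and 0.28 in the authors' deposited table. Most calls were smaller than these, with a median of 0.47 for the positive ones and 0.20 for the smallest (NRARP) in the authors' deposited table. KDM1A, a histone demethylase, had 0.65 (SE 0.10, adjusted p = 5.35e-08), ATP5F1D, an ATP synthase subunit, 0.57 (SE 0.08, adjusted p = 1.04e-08) and the neuropeptide gene GAL 0.54 (SE 0.08, adjusted p = 3.01e-07) in the authors' deposited table. The 1 negative call was a processed pseudogene on chromosome 1 (ENSG00000268903, 135141 to 135895) with a mean count of 25.3, below the limit for named genes and named here after its value was seen. Its log2 fold change was -4.26 (SE 1.15, adjusted p = 0.0487) in the authors' deposited table. Of the 73 calls, 63.0% were among the 10% of genes whose standard errors in Wnt- were largest for their mean count.

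NR1D1 was called in this medium too, with 0.43 (SE 0.10, adjusted p = 0.00829) in the authors' deposited table, and it was the 1 gene called in both media. At an unadjusted p under 0.05, 426 genes had positive and 69 negative folds among the genes with a mean count of at least 10, where chance gives 845 in all. The DESeq2 statistics were thus narrower than a standard normal in Wnt+ (robust SD 0.739) and wider in Wnt- (robust SD 1.17). With the statistic divided by that SD, a choice made after the data were examined, 242 genes were called in Wnt+ and 0 in Wnt-.

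Of the 31 tested lists, 4 were called under Wnt3A-conditioned medium, each to the positive side and by a small amount. The 14 Notch targets had a median of 0.04 (adjusted p = 0.0109, cameraPR), with 2 genes called: HES4, a Notch-induced repressor, at 0.65 (SE 0.15, adjusted p = 0.00694) and NRARP, a feedback inhibitor of Notch, at 0.20 (SE 0.05, adjusted p = 0.0157) in the authors' deposited table. The same 2 passed when adjusted over the list alone. The 32 immediate early genes had a median of 0.04 (adjusted p = 0.0103), with 5 positive at an unadjusted p under 0.05 and 0 called, and 0 when adjusted over the list alone (DESeq2). KLF10 stood at 0.21 (SE 0.07), KLF4 at 0.19 (SE 0.07) and IER5 at 0.18 (SE 0.07) in the authors' deposited table. The 21 TGF-beta and BMP targets had a median of 0.06 (adjusted p = 0.0109), with 1 positive at an unadjusted p under 0.05, SMAD7, and 0 called or passing over the list alone (DESeq2). The 57 developmental regulators bound by Polycomb had a median of 0.03 (adjusted p = 0.0255), with 1 called gene, the homeobox gene EN2 at 0.46 (SE 0.10, adjusted p = 0.00318) in the authors' deposited table. It was also the 1 gene that passed over the list alone. None of these 4 list calls held with a preset correlation of 0.05 (adjusted p = 0.114 for Notch targets, immediate early genes and TGF-beta and BMP targets alike, and 0.264 for the Polycomb-bound regulators). An estimated correlation and fry need values per library and could not be run, so the preset correlation of 0.05 was used instead.

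The remaining 27 tested lists were not called in Wnt+ medium, the lowest adjusted p being 0.0514 for YAP/TAZ targets and for ChREBP and MondoA targets. The ribosomal protein genes had a median of -0.02 (adjusted p = 0.454), with 0 members at an unadjusted p under 0.05 (DESeq2), and the mitochondrially encoded transcripts one of 0.01 (adjusted p = 0.857). SLBP, the histone mRNA binding protein, was the 1 called member of the S phase list, at 0.28 (SE 0.07, adjusted p = 0.0187) in the authors' deposited table. Marker lists of other cell types and of RNA quality were not called in Wnt+: neuronal genes adjusted p = 0.86, fibroblast genes 0.86, blood cell genes 0.886, histone genes 0.886 and nuclear-retained noncoding RNAs 0.634. The same 5 lists had adjusted p between 0.852 and 0.937 in Wnt-. With 4 measured genes, the keratinocyte list was not tested, and its medians were -0.11 and -0.02.

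**Figure D3:**
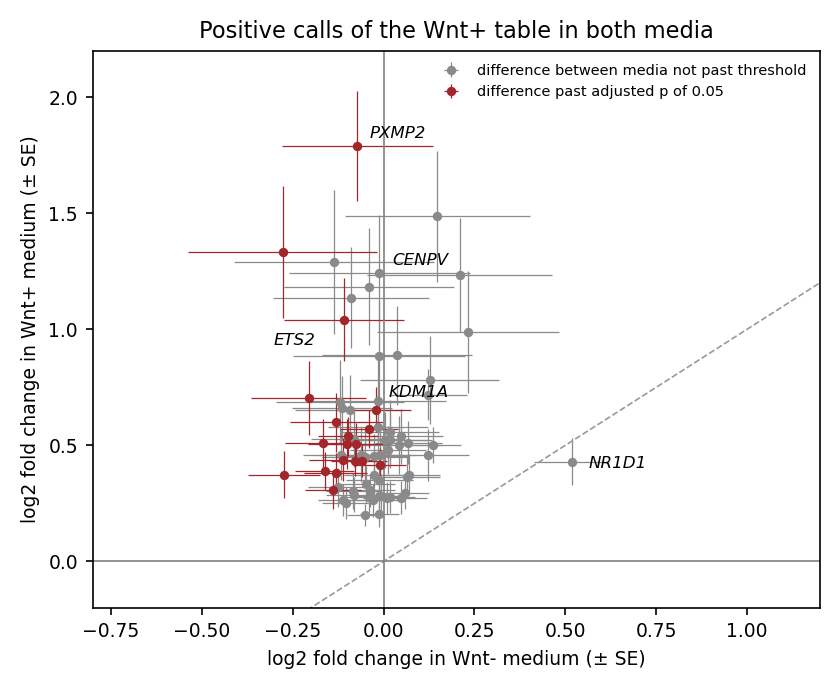
Log2 fold change in Wnt- (x axis) against Wnt+ (y axis) of the 72 positive calls of the Wnt+ table, with standard errors as bars, from the authors' deposited tables. Red points passed the test of the difference between media, and the dashed line marks equal folds. NR1D1 lies near the line at 0.52 and 0.43, while PXMP2 has -0.07 and 1.79, if both tables have the same numerator.

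The fourth comparison asked whether the difference between the arms itself depended on the medium. A z test of the difference between the folds in the authors' deposited tables called 20 genes, all with a more positive fold in Wnt+, and 19 of these were among the 73 calls in Wnt+. At an unadjusted p under 0.05 there were 474 positive and 210 negative differences among 16897 genes, where chance gives 845 in all. With the length, GC content and count trend removed, 8 of the 20 stayed called. If the signs of one table were turned, 8 genes would be called, 3 of them among the 20. PXMP2 differed by 1.86 (SE 0.31, adjusted p = 5.49e-05), ETS2 by 1.15 (SE 0.24, adjusted p = 0.00518), NDUFAF8, an assembly factor of complex I, by 0.91 (SE 0.23, adjusted p = 0.0484) and UBE2S, an E2 enzyme of the anaphase-promoting complex, by 0.73 (SE 0.18, adjusted p = 0.0484). KDM1A differed by 0.67 (SE 0.13, adjusted p = 0.00171), GAL by 0.64 (SE 0.12, adjusted p = 0.000287) and ATP5F1D by 0.61 (SE 0.11, adjusted p = 0.000287). CENPV, ZNF503, NDST2 and C4orf48, although called in Wnt+, did not pass the test of the difference (adjusted p = 0.177, 0.646, 0.164 and 0.0514). NR1D1 differed by -0.09 (SE 0.14, adjusted p = 0.999), or by 0.95 (SE 0.14, adjusted p = 8.01e-07) with one table turned. Of the 73 calls in Wnt+, 23 had a positive and 50 a negative fold in Wnt- in the authors' deposited table, and 3 of them had an unadjusted p under 0.05 there. Across genes, the folds in the authors' deposited tables had a Pearson r of 0.047 and a Spearman rho of 0.0697; genes are not independent replicates.

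Among the lists, the ribosomal protein genes were shifted by 0.24 between media (adjusted p = 8.05e-19, cameraPR) and the mitochondrially encoded transcripts by -0.13 (adjusted p = 6.27e-05). Integrated stress response genes (median 0.07, adjusted p = 0.00447), heat shock genes (0.08, adjusted p = 0.0348) and immediate early genes (0.07, adjusted p = 0.0244) were also called. The calls of these 3 smaller shifts were lost with a preset correlation of 0.05 (adjusted p = 0.141, 0.192 and 0.212). With one table turned, the ribosomal protein genes would differ by -0.28 (adjusted p = 2.5e-22) and the mitochondrially encoded transcripts by 0.15 (adjusted p = 1.71e-05), so their difference in size between media stays and its sign does not. Wnt/beta-catenin targets were not called (median 0.04, adjusted p = 0.652). The effect of Wnt3A-conditioned medium within an arm was not analysed here.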

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

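All results below were singled out because the difference between the aptamer arms was not the same in Wnt- and Wnt+ medium, by a test of that difference that assumes the same numerator in both tables. The tests of library scaling, of the length, GC content and count trend in the ribosomal protein genes, of changes carried by some of the libraries and of the spread of the statistics were chosen after the results were seen, while those of pseudogenes and of the trend in the Wnt+ calls were written before they were run.

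The fold differed between media for 20 genes, each more positive in Wnt+. The differences in log2 fold, computed from the authors' deposited tables, were 1.86 for PXMP2, 1.61 for TMEM54, 1.15 for ETS2, 0.91 for NDUFAF8, 0.73 for UBE2S, 0.68 for FAM174C, 0.67 for KDM1A, 0.65 for GFER, 0.64 for GAL and 0.61 for ATP5F1D. Smaller ones, computed from the authors' deposited tables, were 0.61 for PCSK1N, 0.58 for NKX2-4, 0.55 for SAC3D1, 0.55 for COPRS, 0.51 for C1QBP, 0.51 for TSR3, 0.49 for CREG1, 0.44 for KLHDC2, 0.43 for RNPEP and 0.39 for HRAS. TMEM54 and the genes below GAL other than ATP5F1D, PCSK1N, NKX2-4 and SAC3D1 fall outside the naming rule and are named after their values were seen. Among lists, the difference between media was called for cytosolic ribosomal proteins (adjusted p = 8.05e-19), mitochondrially encoded transcripts (adjusted p = 6.27e-05), the integrated stress response (adjusted p = 0.00447), immediate early genes (adjusted p = 0.0244) and heat shock genes (adjusted p = 0.0348).

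The first pattern weighed is the low position of the ribosomal protein genes in Wnt-. Scaling of the libraries stays open for the list's own direction (-0.26), since DESeq2 holds the median of all genes near 0 (0.0020) whatever the libraries did. Reads moved to pseudogenes would place those above 0, and their median statistic was -0.96. With the trend on length, GC content and count removed, the list's median statistic went from -2.18 to -1.09. The trend may thus be part of the shift. Of matched random lists, 0.01% lay as low, so the trend as fitted was not the whole. Length was that of each gene's longest transcript, so a trend with the length of the RNA present could remain and stays open. Whether some of the libraries carried the shift could not be examined, and a biological effect of the aptamers on these genes was not separately tested.

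The second pattern is that 72 of 73 calls in Wnt+ are positive. Scaling of the libraries is not decided by the median of all genes (-0.0044), which DESeq2 holds near 0. The trend on length, GC content and count left 47 of the 72 calls in place. The called genes had larger standard errors in Wnt- than genes of the same mean count (median log2 ratio 0.277, interval 0.240 to 0.336), as a change carried by some of the libraries of a group could produce, while positive genes at an unadjusted p under 0.05 that were not called had a ratio of 0.0127. The libraries could not be examined singly, and no biological explanation was tested.

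The third pattern is the wider spread of the statistics in Wnt- (robust SD 1.17) than in Wnt+ (0.739). The standard errors were alike, with a median ratio of 0.991, which may follow from 1 estimate of spread shared by libraries that differ in spread. If so, p-values could be too small in Wnt- and too large in Wnt+. No biological explanation was tested.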

How the results depend on the processing

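The filter on the share of summed mean counts, the adjusted p of 0.1, the removed trend, the robust SD, the ranks, the preset correlation of 0.05 and the turned signs of one table were chosen after the data were seen. The 1 gene called in Wnt- became 2 with that filter, 2 with the trend removed, 2 at an adjusted p of 0.1, and 0 with the robust SD, 0 at an adjusted p of 0.01 and 0 at a fold of 1.5. The 73 in Wnt+ became 48 with the trend removed, 242 with the robust SD, 40 at an adjusted p of 0.01 and 22 at a fold of 1.5, and ranged from 54 to 89 otherwise. The 20 differences became 11 without a low-count filter, 9 with the trend removed (8 of the 20 and 1 other), 10 at an adjusted p of 0.01 and 11 at a fold of 1.5. With the signs of one table turned they became 8, with 3 of the 20 kept, and the direction of the difference reversed for cytosolic ribosomal proteins (adjusted p = 2.5e-22), mitochondrially encoded transcripts and glycolysis (1.71e-05 each), the integrated stress response (0.00183), ribosome biogenesis (0.041) and heat shock genes (0.0655), by construction of the setting. No other list called with the signs as deposited or turned reversed. Among genes, NR1D1 went from a difference of -0.09 (not called) to 0.95 (adjusted p = 8.01e-07, z test) with the signs turned. No result reversed under the other alternatives. Of the lists, 7 in Wnt- became 4 with the preset correlation of 0.05 and 4 with the trend removed, 4 in Wnt+ became 2 with ranks, 0 with that correlation and 2 with the trend removed, and 5 for the difference became 2 and 2 with that correlation and the trend removed. Apart from thresholds, which pass fewer or more genes by construction, the cause was not tested. No paired analysis was possible because the labels pair no libraries. Other normalizations (TMM, RLE, upper quartile, library size), fits of 6 libraries, a replicate block, leaving out single libraries, robust=FALSE, DESeq2 against edgeR, camera with estimated correlation, fry and the comparisons of Wnt+ with Wnt- were not run because the count columns could not be tied to samples. Splits of the samples were not possible for the same reason. Depth limits genes with a mean count of 10 to 100 to a median 95% interval of ±0.68 in Wnt-.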

Other observations

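Gene lists in this part were drawn up after the values in Wnt- were seen. The tests of the respiratory chain and of the clock genes were written before they were run. That of the standard errors was chosen after the result was seen. List p-values in this part were not checked with a preset correlation of 0.05, at which all 4 planned list calls in Wnt+ were lost. In Wnt-, 62 of 64 nuclear-encoded respiratory chain and ATP synthase genes had negative folds (median -0.22, adjusted p = 5.51e-31, cameraPR), 46 at an unadjusted p under 0.05 and 36 adjusted over the list alone. UQCRH, a complex III subunit, had -0.27 (SE 0.08) in the authors' deposited table. Mitochondrial ribosomal proteins (62 genes, median -0.17, adjusted p = 2.66e-21), proteasome subunits (32 genes, median -0.15, adjusted p = 1.99e-11) and small nucleolar RNA host genes (18 genes, median -0.15, adjusted p = 6.21e-05) lay on the same side. MRPL36 had -0.29 (SE 0.09), PSMB3 -0.25 (SE 0.09) and SNHG8 -0.32 (SE 0.10) in the authors' deposited table. Zinc finger genes named ZNF lay slightly above other genes (404 genes, median 0.04, adjusted p = 0.000295). In Wnt+ the respiratory chain genes had a median of -0.03 (adjusted p = 0.475), and the difference between media was 0.20 (adjusted p = 4.81e-19). Mitochondrial ribosomal proteins were called negative as a list in Wnt+ too (48 of 62, median -0.03, adjusted p = 0.0107, and 0.0229 with the trend removed, cameraPR). Singly, 1 of the 62 had an unadjusted p under 0.05 there and 0 were called (DESeq2).

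One hypothesis was that the low respiratory chain genes only mirror the trend with length, GC content and count. With that trend removed the list was still called in Wnt- (adjusted p = 2.55e-20, cameraPR), so the trend as fitted is not likely to be the whole of it. The list was chosen from the same values, so its p-value is no independent support. Length was that of the longest transcript, so a trend with the length of the RNA present stays open.

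A hypothesis was that clock genes other than NR1D1 differ with it. The 19 others had a median of 0.08 in Wnt- (adjusted p = 0.0203) and 0.04 in Wnt+ (adjusted p = 0.0107). With the trend removed the adjusted p was 0.133 in Wnt- and 0.0184 in Wnt+. HLF had 0.50 (SE 0.18) in Wnt- and PER1 0.21 (SE 0.08) in Wnt+ in the authors' deposited tables. None of the 19 was called or passed over the list alone in either medium (0 genes, DESeq2), and 2 in each had an unadjusted p under 0.05. Of the 19, 7 had a negative fold in Wnt- and 6 in Wnt+. No difference of the list between media was called (adjusted p = 0.895, cameraPR). A small shift of some clock genes may accompany NR1D1, but the members did not all move with it.

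A further hypothesis was that Wnt targets have higher counts in Wnt3A-conditioned medium, which in a fit with 1 dispersion per gene would lower their standard errors in Wnt+. The ratio of standard errors, Wnt+ to Wnt-, was 0.790 for AXIN2, 0.844 for NKD1, 0.991 for CCND1 and 1.01 for MYC, computed from the authors' deposited tables. The smaller one was in Wnt+ for 25 of 30 Wnt targets, near the share of 74.9% among all genes. The median ratio was 0.969, against 0.992 in random lists, and 0.01% of 10000 random lists of the same mean count lay as low. Higher counts of some Wnt targets in that medium could give this result, but the counts themselves were not used here. Low ratios were not particular to Wnt targets. CYP1A1 (0.566), STC1 (0.666) and CYP1B1 (0.746), outside the list, lay below AXIN2, computed from the authors' deposited tables.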
